A study of Homo sapiens with 6 samples.

How the data were processed

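RNA was measured in 6 LNCaP xenograft tumours, 3 untreated and 3 given external beam radiation in 5 fractions of 10 Gy. LNCaP is an androgen-responsive human prostate cancer line. Per the labels' protocols, whole tumours were homogenized, RNA was purified on RNeasy columns and libraries were made with a TruSeq kit. The labels give a number from 1 to 3 in each group and do not say that the samples came from separate animals, so p-values measure the spread between these samples.

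The deposited values were raw read counts per gene symbol. Per the submitters' processing notes, FastQC, STAR, HTSeq and edgeR were used with the GRCh38 build. Versions, the gene annotation, the strand setting and any removal of mouse reads were not given in the sources used here. A second deposited table, described as normalised, held the same counts as the raw table in 352968 of 352968 cells, so it gave no separate values. Columns were assigned to groups by their names and to replicates by their numbers, which rests on both numberings being the same.

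Library totals ranged from 50133620 to 79252891 counts, so 1 count was worth 0.0126 to 0.0199 CPM (counts scaled to library size). Where all libraries of a group were at 0, a fold was computed against a floor of 3 counts over that group and is given as a lower bound. Such floors cover counting error only. Pairs of libraries within a group differed by more than sampling noise, with chi-square per degree of freedom between 30.7 and 129, so none was treated as a duplicate.

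Counts were analysed in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr on the groups (minimum count 10, minimum total 15), which left 22896 of 58828. Counts were scaled by TMM and tested with the quasi-likelihood F test (estimateDisp, robust glmQLFit in its current form with legacy off, glmQLFTest), two-sided. Calls used a Benjamini-Hochberg adjusted p below 0.05 over all tested genes. The standard error of a log2 fold change was its size divided by the square root of F. CPM are TMM-scaled and given as mean ± SD over 3 libraries. Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 22 lists with 447 members, and again with an estimated correlation and with fry. Tests, gene lists, the rule for named genes and most alternatives were set before the data were examined.

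The rule for named genes took 9 genes of the androgen receptor and p53 pathways, and the 6 highest and 6 lowest log2 fold changes with a symbol, a mean log2 CPM of at least 1 and separated groups. It also took the 2 members of each list with the smallest p, and a set of imaging or therapy targets of prostate cancer. It gave 75 genes, some of which are not reported here. Genes named outside it are said to be chosen after their values were seen.

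The test was checked on simulated counts for irradiated against untreated over 22345 genes. It recovered 14% of genes changed 1.5-fold, 46% at 2-fold, 84% at 4-fold and 98% at 8-fold, and 9.49% of its calls were unchanged genes. There 50 genes were changed at each fold beside the p53 list, while 45.5% of tested genes were called in the real data. With fewer true changes the adjustment is stricter, so these shares do not give the power or false share of the real comparison.

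Gene positions came from GENCODE release 29 on GRCh38, matched by symbol. Of the tested genes 79.3% had a match. A correction for GC content and length over all tested genes, added after the data were seen, was therefore treated as void, because under 80% of the genes had a value. For the analysis along chromosomes, 10235 protein-coding genes with a mean log2 CPM of at least 3 were put in genome order, and the median log2 fold change was taken in 374 windows of 50 genes, moved by 25 genes. Gene order was shuffled 1000 times. A window stood out when it exceeded the 95th percentile of the largest shuffled window, 0.401 from the genome median. The chromosome windows were added after the data were seen. On simulated data for this comparison over 10235 genes with a shift of 0.5 on 1 chromosome, 2 of 15 shifted windows were found with normally distributed values. With the real values in shuffled order, 13 of 15 were found. No other window was called in either case, so the method misses shifts and finding none says little.

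Alternatives were the replicate number as a block, RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood fit, no filter, a stricter filter, a minimum fold, removal of mitochondrially encoded genes and each library left out. Those added later were the value relative to neighbouring genes, a shorter androgen receptor list and removal of markers of other cell types. Pandas and matplotlib were used for summaries and figures.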

Results

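Gene expression was compared between 3 untreated and 3 irradiated LNCaP tumours grown as xenografts. The series concerns androgen receptor activity after radiation, read by imaging of hK2, the kallikrein encoded by KLK2. Untreated libraries held 79252891, 57817538 and 50133620 counts, and irradiated libraries held 52252846, 77520193 and 66843687. CPM below are counts scaled to library size.

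KLK2 was lower in irradiated tumours, at 402 ± 43.9 CPM against 793 ± 230 CPM (SD, n = 3 each). KLK3, which encodes prostate-specific antigen, fell further, from 5796 ± 1121 to 1621 ± 400 CPM. Other androgen receptor targets rose, among them TMPRSS2, a serine protease gene, and FKBP5, which encodes a steroid receptor co-chaperone. The KLK2 and KLK3 changes thus ran opposite to most members of the fixed target list.

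The log2 fold change of KLK2 was -0.98 (SE 0.22, adjusted p = 0.01 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was -1.84 (SE 0.21) for KLK3. TMPRSS2 rose by 1.04 and FKBP5 by 1.89 on the log2 scale. FOLH1, which encodes the imaging target PSMA, had a log2 fold change of -1.08 (SE 0.12). In each of these 5 genes the groups did not overlap, and the exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. KLK2 lies on chromosome 19 at 50861568 to 50880567 and KLK3 at 50854915 to 50860764 (GRCh38).

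**Figure D1:**
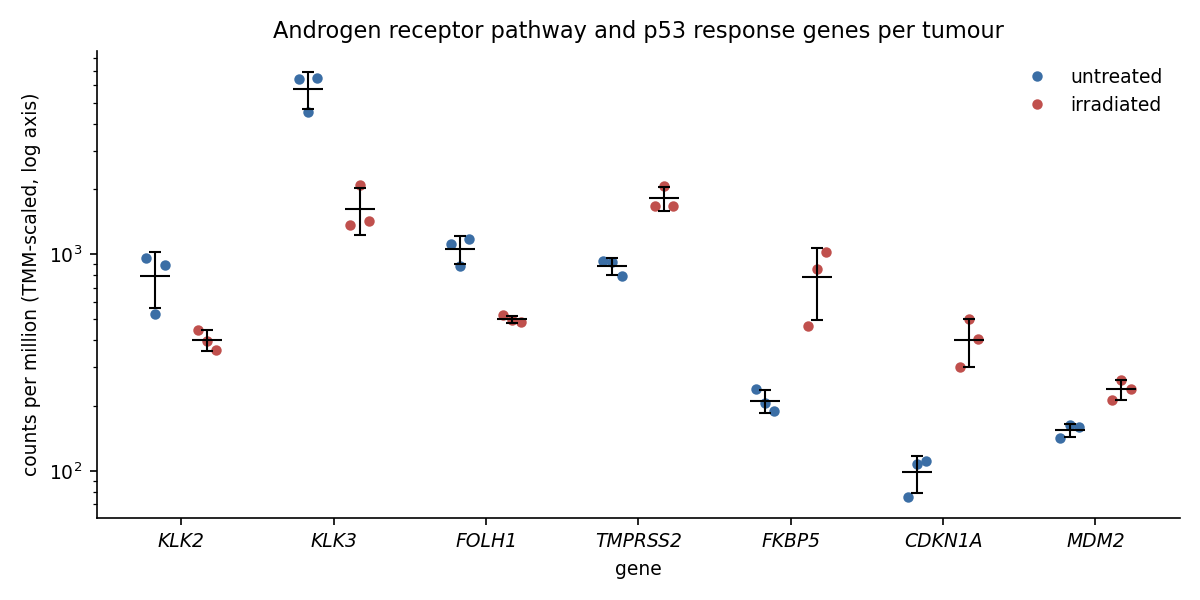
TMM-scaled CPM on a log axis for 7 genes in each tumour. Points are libraries, and black marks with bars are the mean and SD of 3 untreated (blue) or 3 irradiated (red) tumours. KLK2 averaged 793 CPM in untreated and 402 CPM in irradiated tumours, while CDKN1A averaged 98.2 and 403 CPM.

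Of 30 androgen receptor targets, 21 rose, 6 fell and 3 did not pass, with a median log2 fold change of 0.93. Adjusted over the list alone, 21 rose and 6 fell. RHOU (2.41) and KLK4 (1.40) were among those that rose, and TRPM8 (-3.16), a cold-sensing channel gene, was among those that fell. KLK4 and TRPM8 were chosen after their values were seen. The list test gave an adjusted p of 3.25e-05 (camera), and adjusted p = 0.273 with an estimated correlation. Of 10 androgen-repressed genes, 6 fell and 2 rose, the same counts as adjusted over the list alone. OPRK1 fell by 8.99, from 11.4 to 0.0208 CPM, a size that rests on near-zero irradiated levels. UGT2B15, an androgen-inactivating enzyme gene, fell by 3.22. The list's adjusted p was 5.63e-06 (camera) and adjusted p = 0.103 with an estimated correlation.

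Genes of cell division were lower in all irradiated tumours. All 25 mitosis and G2/M genes fell, with a median log2 fold change of -2.92, also when adjusted over the list alone. KIF11, a spindle motor gene, fell by 2.99 and CCNB1, which encodes cyclin B1, fell by 2.72. All 25 DNA replication genes fell, with a median of -1.82, and RRM2, a ribonucleotide reductase gene, fell by 3.94 and GINS1 by 2.81. Of 25 double-strand break repair genes, 16 fell and 2 rose (17 and 3 adjusted over the list alone), and FANCD2 fell by 1.81 while EXO1 fell by 3.44. Adjusted p-values were 8.6e-65, 1.33e-36 and 8.68e-09 (camera). These were adjusted p = 0.0837, adjusted p = 0.0501 and adjusted p = 0.0837 with an estimated correlation. Of 12 tested replication-dependent histone genes 9 rose and 2 fell, the same counts adjusted over the list alone, and HIST1H2AC rose by 3.52 and HIST1H2BD by 2.87. HIST1H3B, chosen after its value was seen, fell by 3.06. Histone genes have near-identical copies, and reads shared between copies leave their single values uncertain. The histone list had an adjusted p of 5.77e-07 (camera), and adjusted p = 0.163 with an estimated correlation.

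Of 30 p53 targets, 16 rose, 3 fell and 11 did not pass (17 and 3 adjusted over the list alone), with a median of 0.50. CDKN1A, a cell cycle inhibitor gene, rose by 2.04 (SE 0.23), GADD45A by 1.00 and MDM2, which encodes a negative regulator of p53, by 0.63. SESN1, a stress response gene, rose from 70.4 to 198 CPM. GDF15, chosen after its value was seen, fell by 1.95. The adjusted p was 0.00705 (camera), and adjusted p = 0.508 with an estimated correlation.

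Interferon and antigen presentation genes went both ways. Of 31 tested interferon response genes, 15 rose, 6 fell and 10 did not pass (16 rose and 7 fell adjusted over the list alone). IFIT2 stood at 3.70, from a low level of 0.562 CPM in untreated to 7.15 CPM in irradiated tumours. STAT2 stood at 1.01, from 72.9 to 147 CPM. PARP14, chosen after its value was seen, stood at -4.47. Of 15 class I presentation genes, 8 rose and 2 fell (9 and 3 adjusted over the list alone), with HLA-E at 1.82 and ERAP2 at 2.17. HLA genes share sequence, so their single values are uncertain. Adjusted p-values were 0.0147 and 0.043 (camera). They were adjusted p = 0.148 and adjusted p = 0.225 with an estimated correlation. The class I call was lost without untreated replicate 1 (adjusted p = 0.0583 by camera) or untreated replicate 2 (adjusted p = 0.0512). Of 17 tested NF-kB and secreted factor genes, 7 fell and 3 rose, also adjusted over the list alone, with LIF at 2.09 and BIRC3 at -2.91, and the list did not pass (adjusted p = 0.216 by camera). Without untreated replicate 1 it did (adjusted p = 0.0403).

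Hypoxia genes were lower in irradiated tumours. Of 21, 18 fell and 1 rose, the same adjusted over the list alone, with a median of -1.33. LOX, a collagen cross-linking enzyme gene, fell by 4.29 and PDK1 by 2.57. The member that rose, NDRG1 (1.51, named after its value was seen), is also in the androgen receptor target list. The adjusted p was 6.9e-12 (camera), and adjusted p = 0.198 with an estimated correlation. Of 16 luminal identity genes, 8 fell and 2 rose, also adjusted over the list alone, with KRT19 at -4.85 and KRT8 at -2.78. Of 9 tested neuroendocrine markers, 3 fell and 1 rose, also adjusted over the list alone, with NTS, a neuropeptide gene, at -8.39 and ENO2 at -4.94. Another 11 of the 20 listed markers were not tested. The median of the tested markers was -0.22. Their median per library, relative to the untreated mean, was -0.08 to 0.18 in untreated and -0.19 to 0.2 in irradiated tumours. Adjusted p-values of the luminal and neuroendocrine lists were 2.37e-05 and 0.000549 (camera), against adjusted p = 0.152 and adjusted p = 0.112 with an estimated correlation. The neuroendocrine call was lost without untreated replicate 3 (adjusted p = 0.125 by camera) and with limma-voom (adjusted p = 0.214).

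Of 28 cytosolic ribosomal protein genes, 24 fell and 0 rose (25 fell adjusted over the list alone), with RPLP0 at -0.86. Of 13 mitochondrially encoded genes, 10 rose and 0 fell, also adjusted over the list alone, with MT-ND6 at 1.20 and MT-ND5 at 1.05. All genes of the mitochondrial genome, these 13 included, together took 5.37 to 5.9% of counts in untreated and 7.64 to 8.39% in irradiated libraries. Adjusted p-values were 1.23e-05 and 0.000601 (camera), against adjusted p = 0.508 and adjusted p = 0.406 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes, which leaves their single values uncertain. Of 24 nuclear oxidative phosphorylation genes, 10 fell and 1 rose, with CYC1 at -0.76 and UQCRFS1 at -0.74. Of 21 lipid synthesis genes, 4 rose and 3 fell, with ELOVL6 at -1.56 and ACACA at 0.73. Of 20 unfolded protein response genes, 8 fell and 5 rose (9 and 5 adjusted over the list alone), with TRIB3 at -2.32 and MANF at -0.89. These 3 lists did not pass (adjusted p = 0.0951, 0.779 and 0.2 by camera). The nuclear oxidative phosphorylation list did, downward, without untreated replicate 3 (adjusted p = 0.00252), with DESeq2 (0.047), with limma-voom (0.0124) and with no filter (0.0121). The unfolded protein list did, downward, with fry (0.0352) and with no filter (0.039).

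**Figure D2:**
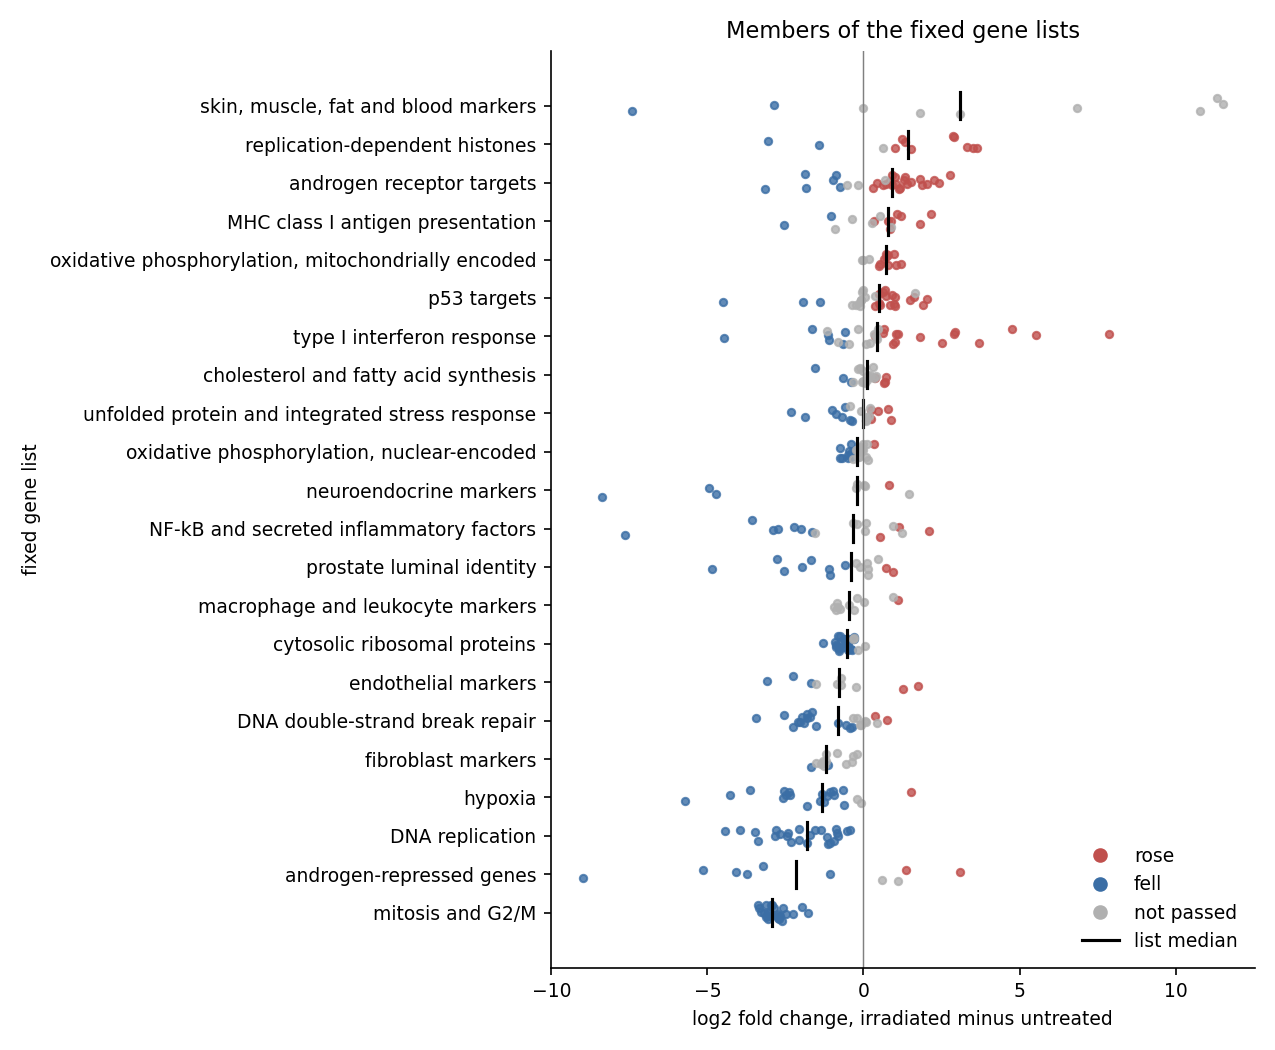
Log2 fold change of each tested member of the 22 fixed lists (irradiated minus untreated, x axis), one row per list. Points are genes, red where they rose, blue where they fell and grey where they did not pass, and black lines are list medians. The mitosis list had a median of -2.92 and the androgen receptor targets one of 0.93.

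Markers of other cell types varied between libraries of a group. Summed fibroblast markers were 913, 1350 and 3000 CPM in untreated and 1010, 335 and 781 CPM in irradiated tumours. Of 14 such markers 2 fell, LUM (-1.15) and POSTN (-1.70), and adjusted over the list alone 1 fell. Of 10 endothelial markers, 3 fell and 2 rose, with VWF at -3.08 and EGFL7 at 1.75. Of 11 macrophage and leukocyte markers 1 rose, CD68 (1.11), and adjusted over the list alone 0 rose. ITGAM stood at 0.95 without passing. Both were low, CD68 at 0.366 CPM in untreated and 0.811 CPM in irradiated tumours, and ITGAM at 0.293 and 0.569 CPM. Of 9 skin, muscle, fat and blood markers 2 fell, KRT14 (-2.85) and HBB (-7.41), and the sums were 953, 1820 and 3400 CPM in untreated and 4740, 40.2 and 61.3 CPM in irradiated tumours. For that list the median was 3.09 while the test pointed down. These 4 lists did not pass (adjusted p = 0.0846, 0.2, 0.779 and 0.655 by camera). The fibroblast list passed, downward, without untreated replicate 1 (0.0109), untreated replicate 2 (0.0231) or irradiated replicate 3 (0.0483). With all 6 libraries it passed with limma-voom (0.0193) and with no filter (0.00734). The endothelial list passed, downward, without irradiated replicate 1 (0.0497). The calls of POSTN and CD68 were each lost with 1 library left out, untreated replicates 2 and 3 and irradiated replicate 3 for both and irradiated replicate 2 for CD68, with adjusted p up to 0.0586 and 0.079 by edgeR. With all 6 libraries POSTN was not called with no filter (adjusted p = 0.0886 by edgeR), nor CD68 with DESeq2 (adjusted p = 0.0551). How reads of the mouse host were handled was not given in the sources used here. A rise or fall of these markers therefore cannot be assigned to human or to host transcripts.

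Among other imaging or therapy targets, TMEFF2 (-5.13), GRPR (-7.01) and PSCA (-0.73) fell, and STEAP2 (0.73) and CD46 (1.10) rose. STEAP1 (0.10), CD276 (-0.08), DLL3 (0.03) and SSTR2 (0.82) did not pass. PSCA was not called without untreated replicate 1 or 2 or irradiated replicate 3 (adjusted p up to 0.0647 by edgeR), and SSTR2 was called without irradiated replicate 1 (0.0293). Among the largest changes, PASD1 (11.24), SLC25A43 (10.56), CNTNAP3 (9.24), SLC6A3 (9.23), KRT6A (8.53) and LINC01029 (8.49) were higher. These values rest on near-zero untreated levels, and those of CNTNAP3, SLC6A3, KRT6A and LINC01029 moved with single libraries. With 1 library left out, PASD1 stayed at 10.8 to 11.6 and SLC25A43 at 10.1 to 10.9. Without untreated replicate 1, CNTNAP3 stood at 11.07, SLC6A3 at 8.61, KRT6A at 7.85 and LINC01029 at 7.74. SLC6A3 stood at 10.02 and KRT6A at 11.24 without untreated replicate 2, LINC01029 at 9.30 without untreated replicate 3, and SLC6A3 at 7.73 and KRT6A at 7.22 without irradiated replicate 3. GPC5-AS1, KCNK17, UBE2Q2P1 and FOXB2 had 0 counts in all irradiated tumours and were at least 1240-fold, 863-fold, 299-fold and 264-fold lower. Without irradiated replicate 2 these bounds were 756-fold, 525-fold, 182-fold and 161-fold, and without irradiated replicate 3 they were 817-fold, 568-fold, 197-fold and 174-fold. KCNK17 lay at 25.3, 6.41 and 2.48 CPM in untreated tumours, and its bound was 299-fold without untreated replicate 1. SLITRK3 (-11.30) and TRPA1 (-10.86) fell too. SLITRK3 stood at -13.15 without irradiated replicate 3, and TRPA1 at -8.71 without untreated replicate 3 and -12.65 without irradiated replicate 2. KCNK17 was not called without untreated replicate 2 or any 1 irradiated replicate (adjusted p up to 0.105 by edgeR), nor TRPA1 without any 1 irradiated replicate (up to 0.195), nor KRT6A without untreated replicate 2 (0.0736). With all 6 libraries the KCNK17 call was lost with no filter (adjusted p = 0.184 by edgeR), and that of TRPA1 with no filter (adjusted p = 0.0852) and with limma-voom (adjusted p = 0.0513). UBE2Q2P1 is a pseudogene and GPC5-AS1 an antisense gene, so both are uncertain.

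Over all genes, 10421 of 22896 (45.5%) changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5645 higher and 4776 lower. By 2-fold or more, 2686 were higher and 2530 lower. The groups did not overlap for 56.5% of genes, where chance gives 10%. The correlation of log2 CPM across genes was 0.978 to 0.987 within untreated, 0.961 to 0.984 within irradiated and 0.893 to 0.92 between groups. The labels separate the groups by treatment, and none gives a batch.

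Log2 fold changes were also shifted along whole stretches of chromosomes, an analysis added after the data were seen. The SD of window medians was 0.223, against at most 0.112 in 1000 shuffled gene orders. In all, 11 stretches with 1100 genes stood out. Chromosome 20 from 0.3 to 20.7 Mb was lower by a median of -0.72 (75 genes), and chromosome 19 from 45.7 to 58.6 Mb by -0.54 (200 genes). KLK2 and KLK3 lie in the latter. Chromosome 9 from 0.0 to 97.9 Mb was higher by 0.45 (175 genes). On chromosome 20 the irradiated tumours stood at -0.64, -0.77 and -0.64, and each untreated tumour within 0.06 of the others of its group. Window medians also varied beyond shuffling within groups. The pairs compared there were untreated 1 and 3 each against untreated 2, and irradiated 1 and 2 each against irradiated 3. Untreated 1 against 3 and irradiated 1 against 2 were not compared, so larger values may be missing. These pairs had the highest chi-square per degree of freedom of their groups, 61.7 and 129. In the pairs compared the SDs were smaller, 0.043 to 0.133 against 0.211 to 0.242 between same-numbered libraries of the 2 groups. Relative to the mean of their own shuffles they were 1.64 to 3.05 times as large within groups and 2.19 to 2.32 times between groups, with 13 to 38 and 31 to 42 windows standing out. Neighbours were taken as the 50 nearest of the genes used for windows, with kallikrein genes left out. Against their median (-0.51), KLK2 was lower by -0.47 (SE 0.23) and KLK3 by -1.33 (SE 0.23). KLK4, in the same stretch, was higher than that median by 1.91 (SE 0.13). These SE cover the gene's own error and that of the median, not the spread between neighbours.

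**Figure D3:**
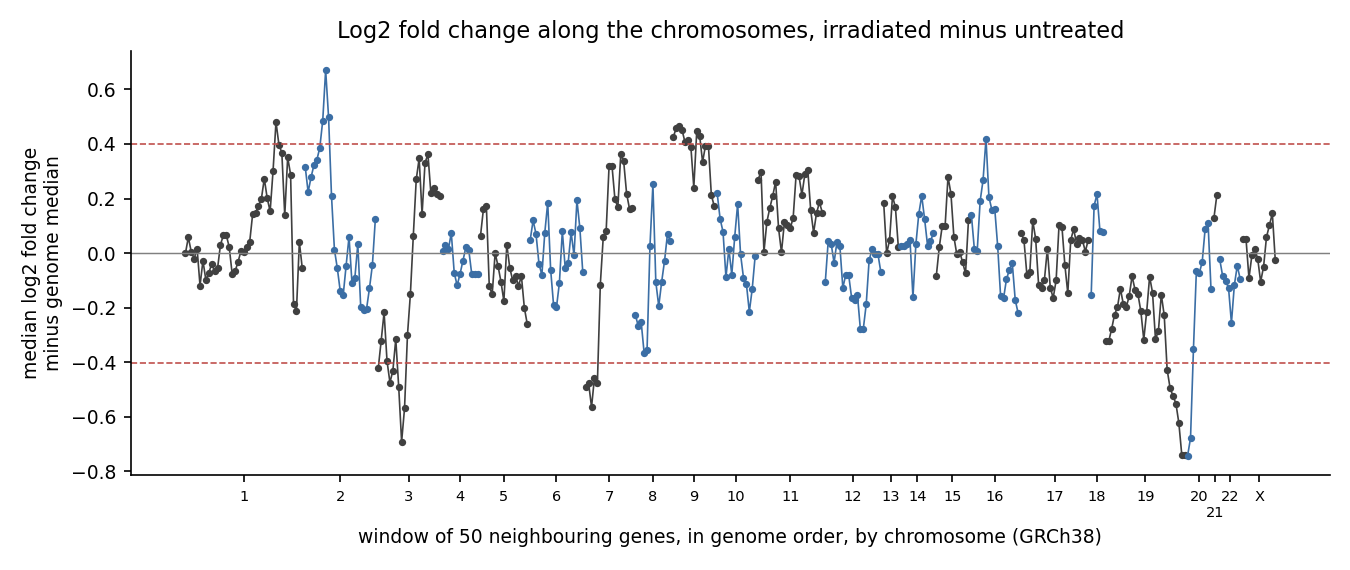
Median log2 fold change (irradiated minus untreated) in 374 windows of 50 neighbouring genes, minus the genome median, in chromosome order. Points are windows, and dashed lines at 0.401 above and below 0 mark the 95th percentile of the largest window in shuffled gene orders. The low windows on chromosome 20 belong to the stretch with a median of -0.72.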

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

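Comparisons with neighbouring genes, the shorter androgen receptor list and the removal of other cell types' markers were chosen after the results were seen. The number of changed genes stayed between 8239 and 11103 with 1 library left out (3926 to 5948 higher, 4004 to 5177 lower). With the replicate block it was 9576, of which 9285 were shared with the 10421, and with DESeq2 10340. Same-numbered libraries did not deviate together (r = -0.249, 0.154 and 0.102), and not each correlated best with its own number. With a log2 fold change of at least 1 required, 5216 genes remained (2686 higher, 2530 lower) by construction, and KLK2, at -0.98, was no longer called, nor were other named genes below that size. No called value reversed. With 1 library left out, KLK2 ranged from -1.22 to -0.82 and KLK3 from -2.13 to -1.72. Relative to its neighbours KLK2 stood at -0.47, no longer clear of 2 standard errors. With an estimated correlation, the androgen receptor, p53 and mitosis lists had adjusted p of 0.273, 0.508 and 0.0837, and 0 of the 19 other lists passed, against 11. Only 4 residual degrees of freedom were left, and the cause of that loss was not tested. With fry, the same 3 lists had adjusted p of 0.00346, 0.00976 and 0.00014, and every list called by camera passed. Fry tests whether a list's genes changed, not whether they changed more than other genes. With 45.5% of all tested genes called, passing it says less. No scaling moved the median of all genes by over 0.1 or the share of higher calls by over 10 percentage points. Among named genes, calls were lost 18 times with 1 library left out and 15 times under other alternatives, and 1 was gained. The planned tests on the normalised table were not run because it equals the raw table, and the GC correction over all tested genes was void at 79.3% coverage. In the simulation 46% of 2-fold changes were recovered. Far fewer genes were changed there than were called in these tumours, so that share does not give the power here.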

Other observations

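Tests of KLK2 and KLK3 against neighbours, of the tumour share and of genes near zero were chosen after their results were seen, and the chromosome pattern itself was found in these data. Outside the rule for named genes, and chosen after their values were seen, ETV1 (a transcription factor gene, log2 fold change -9.95), CFLAR (-8.19) and SCHLAP1 (-9.65) were far lower in irradiated tumours, and P2RY1 (8.20) was far higher. By set limits, 24 genes were at 10 CPM or more in each untreated tumour and under 0.5 CPM in each irradiated one, and 11 genes the other way. CFLAR, SCHLAP1 and P2RY1 were among them, and ETV1 was not. The 9 other splits of the 6 libraries gave 0 genes that met these limits. Each of those splits mixes untreated and irradiated libraries on both sides, so genes that differ by group cannot be counted there.

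Of 10 splits of the 6 libraries, 1 gave 10421 changed genes, which was the real split itself, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.

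For the shifted chromosome stretches, a smooth trend on GC content and length explained 0.9% of the variance of log2 fold changes, so its removal moved little, and the SD of window medians was 0.227 afterwards. Without related neighbouring genes the SD was 0.215, and both values lay above every shuffled order, as did those of comparisons within groups. Contrasts that shared no library had a lowest correlation of 0.83, which argues against a single outlying library. In stretches picked on irradiated 1 and untreated 1, 80.6% of genes lay on the same side in the other 4 libraries, which is consistent with gene dosage that differs between the groups. Only RNA was measured, and libraries of 1 group differed along chromosomes too, so regional control of expression stays open, as does whether such a difference came from radiation or preceded it.

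For KLK2, lower dosage of its stretch may account for much of the fall: it lay -2 standard errors from its neighbours, at the bound set, so this cannot be told apart from a fall of its own. KLK3 lay -5.81 standard errors away. KLK4, a kallikrein gene of the same stretch and so not counted as a neighbour, lay 15.11 standard errors above them. These standard errors leave out the spread between neighbours, whose quartiles were -0.865 and -0.12. Of the 50 neighbours, 11 were lower than KLK2 and 1 was lower than KLK3, which argues against dosage alone as the cause for KLK3. Against a lower share of tumour cells as the cause of either fall, the median of 27 other androgen receptor targets was 0.93. These targets may themselves change within tumour cells, and of 16 luminal identity genes 8 fell and 2 rose. The median therefore does not exclude a lower share as part of the falls.

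For the genes near zero, neighbours were examined only for those near zero in irradiated tumours. Of these neighbours 0 of 44 (0%) were near zero too, which argues against loss of long stretches of DNA for those genes. The median residual in irradiated tumours was 0.261%, but choosing genes under 0.5 CPM caps it at 5%, so it does not test whether cells of the untreated kind remained. A candidate explanation is another stock or clone of cells in one group, which cannot be told apart from an effect of radiation, because each group holds its own tumours. Within groups, 13 genes were present in irradiated 1 and near zero in both others, among them the muscle genes RYR1, MYBPC2, MYH6 and MYH7, chosen after their values were seen. That library also held the highest sum of skin, muscle, fat and blood markers (4740 CPM against 40.2 and 61.3 CPM), so these genes do not count against another stock.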
